A study of Mus musculus with 6 samples.

How the data were processed

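Femoral arteries from 6 mice were profiled, 3 treated with saline and 3 with vasostatin-2, at day 3 after wire injury. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was enriched with oligo(dT) beads, and libraries were sequenced on a BGISEQ instrument. The labels name vascular smooth muscle cells as the cell type, but the protocols describe RNA from the whole injured artery. The submitters' processing notes name HISAT2 2.1.0, DESeq2 1.26.0 and the genome build GRCm38.p6. The tool that turned alignments into counts is not given in the sources used here, nor is strandedness, so reads of overlapping and antisense genes could not be separated.

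The deposited table holds 18476 genes, each with an estimated count per library that need not be whole; 65.6% of the deposited estimated counts were exactly whole numbers. The authors also deposited FPKM and TPM values for each library, which were not used for tests. The authors' log2 fold changes, p-values and q-values from DESeq2 were deposited in the same table, and are quoted only where the authors' deposited table is named. A positive log2 value there means higher with vasostatin-2. Its sign matched that of the group means in 99.3% of the rows whose genes passed the low-count filter used here. The table held 0 genes of the mitochondrial chromosome, so the mitochondrial share could not be used as a sign of RNA quality.

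Estimated counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr, which left 14557, and libraries were scaled by TMM, with factors between 0.985 and 1.01. The quasi-likelihood test was run in edgeR 4.0.16 (R 4.3.3) with robust dispersion estimates and treatment as the only term, and p-values were adjusted by Benjamini-Hochberg. The biological coefficient of variation was 16.1%. CPM values use the scaled library sizes, and log2 CPM values use a prior count of 2. DESeq2 1.42.0 and limma-voom with quality weights (limma 3.58.1) were run on the same genes. DESeq2 left 584 adjusted p-values undefined. Lists were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry. Python 3 with pandas and matplotlib read the table and drew the figures.

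The test, the 36 lists and the rule for named genes were fixed before the data were examined. The rule took, in each direction, 6 genes past the adjusted threshold with the largest change, with a mean of at least 1 CPM and no overlap between groups. As no gene passed, it took the 6 with the smallest unadjusted p under the same conditions. It added 2 members from each of the 8 lists with the smallest camera p, by mean expression where no member was called, and Chga by name. Some items the rule or the lists cover are not reported here. Alternatives fixed at the same time were other scalings, other low-count filters, replicate number as a block, leaving out each replicate, removal of muscle, fat and red cell genes, other thresholds and other tests. Further alternatives were added after the data had been seen: bias-adjusted dispersions, DESeq2 on all genes and without single replicates, leaving out saline replicate 3 and vasostatin-2 replicate 3 together, because Schwann and skeletal muscle transcripts stood out there, and the erythroid level as a covariate.

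In 3 sets of simulated counts for this comparison with known changes, over 14433 genes, edgeR called 72.6% of genes changed 2-fold and 92.9% of those changed 4-fold, and DESeq2 80.5% and 94.6%. Over the 3 sets edgeR made 40 false calls beside 212 and 274 calls of genes changed 2-fold and 4-fold. DESeq2 made 145 false calls beside 235 and 279 such calls. The false share of DESeq2's calls was thus larger than edgeR's, and larger than the adjusted threshold allows. Each gene was drawn independently there, without variation shared between genes of a library, so these shares need not hold for the real libraries. A count of 0 in the real data therefore does not show that 2-fold changes are absent. The libraries of a group differed by far more than counting noise, so no library was counted as a duplicate. The 3 libraries of a group are described as biological replicates, and p-values of single genes measure the spread between these samples. Camera at the preset correlation treats the genes of a list as nearly independent, so its p-values do not measure that spread. An exact permutation of the list means over libraries gave p = 0.9 for skeletal muscle and 0.4 for contractile smooth muscle and NF-kB feedback. It gave 0.1 for neutrophil, hypoxia and glycolysis, oxidative stress and leukocyte adhesion, and between 0.2 and 0.3 for the other lists camera called. An exact test of a single value over 3 against 3 libraries cannot go below 0.1. Chance alone gives that value in 10% of lists, and no further list of the 36 tested reached it.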

Results

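Gene expression was measured by bulk RNA sequencing in injured femoral arteries of wild-type C57BL/6 mice, taken 3 days after a guide wire had been used to damage the vessel. The arteries had been treated from outside, around the vessel, with vasostatin-2 or with saline. Vasostatin-2 is a fragment of chromogranin A, the secretory-granule protein encoded by Chga. There were 3 libraries per group, described by the submitters as biological replicates, and all 6 belonged to 1 batch. Total estimated counts were 20105995, 19333730 and 19807214 in the saline libraries and 19400272, 19895152 and 19901763 in the vasostatin-2 libraries, so depth was nearly equal between groups. At this depth 3 counts correspond to between 0.149 and 0.155 CPM, the count scaled to the size of the library. The comparison addressed which genes differ in the injured artery after local vasostatin-2 treatment.

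The 6 higher genes named first had the smallest unadjusted p among genes with a mean of at least 1 CPM and no overlap between groups. Dlk1, a transmembrane protein of progenitor and stromal cells, was at 31.6 ± 6.16 CPM with vasostatin-2 and 4.84 ± 2.58 CPM with saline (SD, n = 3 each), a log2 fold change of 2.70 (SE 0.40). Crabp1, a retinoic acid-binding protein, was at 68.0 ± 11.6 CPM against 19.5 ± 4.56 CPM (log2 fold change 1.80, SE 0.20). Agtr2, the angiotensin II type 2 receptor, was at 14.9 ± 3.83 CPM against 3.35 ± 1.08 CPM (log2 fold change 2.15, SE 0.28). Nptx1, a secreted pentraxin best known from neurons, was at 4.07 ± 0.466 CPM against 0.861 ± 0.0352 CPM (log2 fold change 2.23, SE 0.21). Smpd3, which encodes neutral sphingomyelinase, and Mid1ip1, a regulator of lipid synthesis, had log2 fold changes of 1.00 and 0.40. In the coordinates of the deposited table (GRCm38.p6), Dlk1 lies on chromosome 12 from 109452485 to 109463336, Crabp1 on chromosome 9 from 54764748 to 54773110, Agtr2 on chromosome X from 21484549 to 21488833 and Nptx1 on chromosome 11 from 119538719 to 119547820. By that choice every vasostatin-2 library lay above every saline library in each of the 6.

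On the lower side, chosen the same way, Ndufa4l2, a hypoxia-induced mitochondrial protein, was at 11.2 ± 0.686 CPM with vasostatin-2 and 20.5 ± 1.88 CPM with saline (log2 fold change −0.87, SE 0.10). Gcnt2, a glycan-branching enzyme, was at 49.5 ± 1.34 against 73.8 ± 4.60 CPM (log2 fold change −0.58, SE 0.07). Cfap53, a cilia-associated gene, was at 168 ± 8.38 against 254 ± 8.08 CPM (log2 fold change −0.59, SE 0.07). Spata13, Olfr1033 and Zfp729a had log2 fold changes of −0.65, −0.66 and −0.46. Olfr1033 and Zfp729a belong to multigene families whose members share sequence, so their counts are uncertain. Cfap53, Gcnt2, Spata13, Olfr1033, Zfp729a, Smpd3 and Mid1ip1 each have an entry of RNAcentral, a database of non-coding RNA, among their deposited transcripts. So do 9461 of the 18476 genes when all are taken. Whether such entries took up reads counted for these genes was not tested.

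None of these 12 genes passed the test applied. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14557 genes at an adjusted p of 0.05, and the lowest adjusted p was 0.198, for Nptx1. At an unadjusted p of 0.05 the same test gave 1040 genes, 479 higher and 561 lower with vasostatin-2, or 7.14% of those tested. DESeq2 with Benjamini-Hochberg adjustment called 113 genes, 49 higher and 64 lower. In the simulated counts a larger share of its calls than of edgeR's was false, and larger than the adjusted threshold allows. All 12 genes above were among the 113. They had been picked for small p and no overlap in the same counts, so this is no independent support. limma-voom with quality weights called 0. Leaving out saline replicate 2 gave 2 genes with edgeR, Gpnmb (log2 fold change 2.20) and Igfbp3 (log2 fold change −1.55), named here because they were the 2 called and not by the rule for named genes. DESeq2's count was 262 without saline replicate 2, 25 without vasostatin-2 replicate 2 and 66 without vasostatin-2 replicate 3. In 1861 genes (12.8%) the libraries of the groups did not overlap, where chance alone gives 10%.

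**Figure D1:**
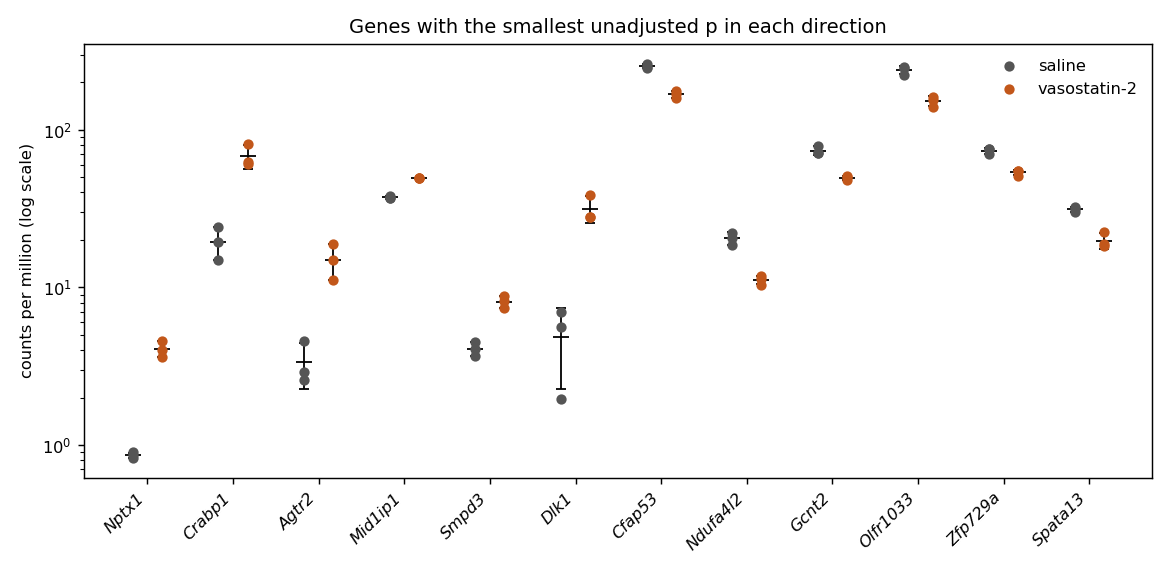
CPM, on a log axis, of the 6 genes in each direction with the smallest unadjusted p among genes without overlap between groups; each point is 1 library, horizontal bars are group means and vertical bars are SD (n = 3 per group). None of the 12 genes passed edgeR's adjusted test.

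Of 36 gene lists for pathways and cell types, limma's camera with a preset correlation of 0.01 called 13 at a Benjamini-Hochberg adjusted p of 0.05. Genes of neutrophils, glycolysis and the hypoxia response, T and NK cells, red cells and oxidative stress fell as groups. So did those of inflammatory cytokines, NF-kB feedback, alternatively activated macrophages and leukocyte adhesion, 9 lists in all. Genes of monocytes and macrophages, skeletal muscle, contractile smooth muscle and complement rose as groups, 4 lists in all. With an estimated correlation camera called 0 of the 36 lists, 2 had an unadjusted p below 0.05, and the lowest adjusted p was 0.514. fry called 0 lists in 1 direction.

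The neutrophil list fell by a median of 1.12 on the log2 scale, with 17 of 18 members lower (camera adjusted p = 1.10e-09; adjusted p = 0.514 with an estimated correlation). With the erythroid level as a covariate its median was −0.45 (camera adjusted p = 0.00731). The erythroid mean itself differed between groups, at 3.50 log2 CPM with vasostatin-2 and 5.52 with saline. That covariate can therefore also take up a treatment effect. Values with it, here and below, cannot separate blood content from treatment. No member of the neutrophil list passed edgeR over all genes, 5 passed adjusted over the list alone, and DESeq2 called 4. Csf3r, the receptor for granulocyte colony-stimulating factor, was at 163 ± 33.5 CPM with vasostatin-2 and 233 ± 48.8 CPM with saline, a log2 fold change of −0.51 that was −0.29 with that covariate. Clec4d, a myeloid lectin receptor, was at 47.0 ± 4.76 against 90.9 ± 42.9 CPM. Its log2 fold change was −0.95, but −0.49 without saline replicate 2 and −0.27 with the covariate. The erythroid list fell by a median of 2.42 (8 of 9 members lower; camera adjusted p = 5.99e-05; adjusted p = 0.514 with an estimated correlation) and moved with the neutrophil list. Its median was −1.08 without saline replicate 2 and −4.02 without vasostatin-2 replicate 1, and −0.017 with its own level as the covariate (camera adjusted p = 0.806). Its haemoglobin gene Hbb-bs was at 4593 CPM in saline replicate 2, between 656 and 867 CPM in the other saline libraries and in vasostatin-2 replicate 1 (843 CPM), and at 133 and 108 CPM in vasostatin-2 replicates 2 and 3. Hba-a1 followed the same order, with 1880 ± 1998 CPM in saline and 351 ± 391 CPM with vasostatin-2. The T and NK cell list fell by a median of 0.39, with 16 of 18 members lower (camera adjusted p = 1.52e-05; adjusted p = 0.514 with an estimated correlation). Cd4 was at 9.03 ± 1.92 against 17.3 ± 10.03 CPM, while Il7r was at 25.0 ± 3.93 against 23.3 ± 18.3 CPM. The log2 fold change of Cd4 was −0.94, but −0.42 without saline replicate 2 and −0.22 with the covariate. That of Il7r was 0.10, but 0.97 without saline replicate 2, −0.23 without saline replicate 3 and 1.00 with the covariate.

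The hypoxia and glycolysis list fell by a median of 0.22 with 23 of 24 members lower (camera adjusted p = 5.38e-09; adjusted p = 0.514 with an estimated correlation). Its median was −0.35 without vasostatin-2 replicate 3, −0.43 without both replicates 3 and −0.35 with the erythroid level as a covariate. Adjusted over the list alone, 7 members were lower by edgeR, and DESeq2 called 3. The glycolytic enzymes Gapdh and Pkm were at 2124 ± 200 and 1013 ± 98.6 CPM with vasostatin-2, against 2437 ± 139 and 1267 ± 104 CPM with saline. The log2 fold change of Gapdh was −0.20, and −0.35 with the covariate. The oxidative stress list fell by a median of 0.17 with 17 of 22 members lower (camera adjusted p = 4.17e-04; adjusted p = 0.579 with an estimated correlation), 5 of them adjusted over the list alone. Hmox1, which breaks down haem, was at 533 ± 219 against 966 ± 153 CPM, and Gpx3, a secreted glutathione peroxidase, was at 613 ± 86.7 against 767 ± 91.0 CPM. Without saline replicate 2 the oxidative stress list's median was −0.08 and its camera adjusted p was 0.139, and with the erythroid level as a covariate they were −0.021 and 0.346. That covariate took the log2 fold change of Hmox1 from −0.86 to −0.25 and that of Gpx3 from −0.32 to −0.13.

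Inflammatory cytokines and chemokines fell by a median of 0.40 with 26 of 29 members lower (camera adjusted p = 4.17e-04; adjusted p = 0.514 with an estimated correlation). Their most abundant members, the chemokines Ccl6 and Ccl9, were at 889 ± 163 and 502 ± 52.4 CPM with vasostatin-2 against 1194 ± 438 and 658 ± 241 CPM with saline. The log2 fold change of Ccl6 was −0.43, but −0.11 without saline replicate 3 and −0.65 without saline replicate 1. That of Ccl9 was −0.39, but −0.13 without saline replicate 2, −0.65 without saline replicate 1 and −0.092 with the erythroid level as a covariate. NF-kB feedback genes fell by a median of 0.20 with 15 of 18 members lower (camera adjusted p = 0.00775; adjusted p = 0.745 with an estimated correlation). Nfkb2 was at 107 ± 5.01 against 120.0 ± 16.3 CPM, and Nfkb1 at 122 ± 1.58 against 118 ± 9.10 CPM. The log2 fold change of Nfkb2 was −0.17, but −0.092 without saline replicate 1 and −0.27 without saline replicate 3. That of Nfkb1 was 0.048, but 0.094 without saline replicate 1 and −0.013 without saline replicate 2. Alternatively activated macrophage genes fell by a median of 0.32 (9 of 11 lower, 2 of them adjusted over the list alone) and leukocyte adhesion genes by a median of 0.13 (15 of 17 lower), both with a camera adjusted p of 0.00954 and an adjusted p = 0.514 with an estimated correlation. Single libraries decided several of these calls and medians. Without saline replicate 1 the cytokine median was −0.13 (camera adjusted p = 0.0512) and the NF-kB feedback median −0.08 (camera adjusted p = 0.346), while without saline replicate 3 the NF-kB feedback median was −0.35. The leukocyte adhesion median was −0.07 without saline replicate 2 (camera adjusted p = 0.0615). For alternatively activated macrophages the median was −0.031 without saline replicate 3 (camera adjusted p = 0.201), −0.28 without vasostatin-2 replicate 3 (camera adjusted p = 0.0657) and −0.51 without vasostatin-2 replicate 1. With the erythroid level as a covariate the calls for NF-kB feedback (median −0.14, camera adjusted p = 0.0791) and alternatively activated macrophages (median −0.18, camera adjusted p = 0.303) were lost.

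The monocyte and macrophage list rose by a median of 0.19 with 17 of 23 members higher (camera adjusted p = 0.00374; adjusted p = 0.514 with an estimated correlation). C1qb, a complement component made by macrophages, was at 1019 ± 86.0 against 807 ± 89.5 CPM, and Lyz2, the myeloid lysozyme, at 3751 ± 319 against 3684 ± 1213 CPM. The log2 fold change of Lyz2 was 0.026, but 0.33 without saline replicate 2, −0.14 without saline replicate 1 and 0.49 with the erythroid level as a covariate. The list's median was 0.34 without vasostatin-2 replicate 1, and its camera adjusted p was 0.0712 without saline replicate 3 and vasostatin-2 replicate 3. The complement list rose by a median of 0.12 with 14 of 20 members higher (camera adjusted p = 0.0317; adjusted p = 0.514 with an estimated correlation). Its median was 0.049 without saline replicate 1 and 0.044 without vasostatin-2 replicate 1, with camera adjusted p values of 0.346 and 0.121. The call was also lost without saline replicate 2 (adjusted p = 0.0514) and without vasostatin-2 replicate 2 (adjusted p = 0.0534), where the medians were 0.14 and 0.11. The median was 0.22 without saline replicate 3 and with the erythroid level as a covariate, and 0.20 without both replicates 3.

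The contractile smooth muscle list rose by a median of 0.34 with 22 of 25 members higher (camera adjusted p = 0.00930; adjusted p = 0.914 with an estimated correlation). The list's mean was lowest in saline replicate 2 and vasostatin-2 replicate 1, at 4.37 and 4.43 log2 CPM, and highest in vasostatin-2 replicates 2 and 3, at 5.35 and 5.48. Its camera adjusted p was 0.411 without saline replicate 2, 0.119 without vasostatin-2 replicate 2 and 0.294 without vasostatin-2 replicate 3, with medians of 0.23, 0.23 and 0.22. The median was 0.56 without saline replicate 3 and 0.61 without vasostatin-2 replicate 1. With the erythroid level as a covariate the direction turned, with a median of −0.52 and a camera adjusted p of 2.73e-04. As that level differed between groups, the turn cannot be assigned to blood. The skeletal muscle list rose by a median of 1.51 with all 26 tested members higher (camera adjusted p = 0.00875; adjusted p = 0.914 with an estimated correlation), and this rested on vasostatin-2 replicate 3. Its mean there was 4.84 log2 CPM, against values from 1.70 to 2.25 in the other 5 libraries, and without that library the list's median was −0.29, with a camera adjusted p of 1.12e-07 in the lower direction. Without saline replicate 3 its camera adjusted p was 0.0863. With the erythroid level as a covariate its median was −0.39 and its camera adjusted p 0.178.

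**Figure D2:**
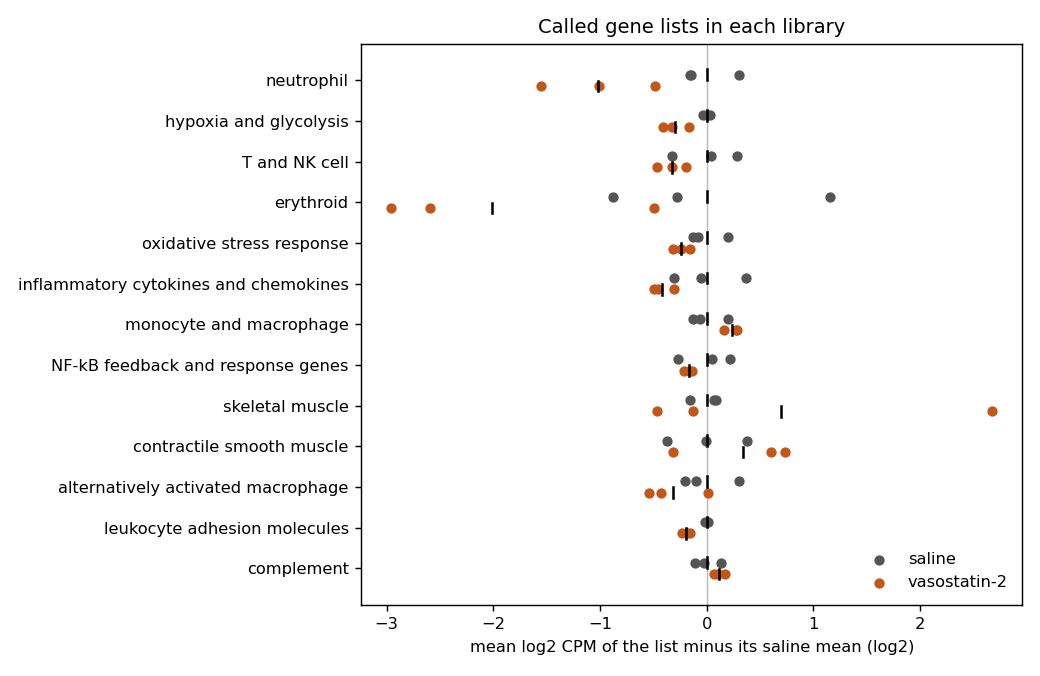
Mean log2 CPM of each of the 13 called lists in each library, minus the list's saline mean; points are libraries and vertical bars are group means (n = 3 per group). All 3 vasostatin-2 libraries lie below all 3 saline libraries for 4 lists (neutrophil, hypoxia and glycolysis, oxidative stress and leukocyte adhesion). These 4 are the only lists without overlap among all 36 tested. Chance alone gives 10%, so their number is close to that of chance. The other 9 called lists overlap, and 1 vasostatin-2 library carries the skeletal muscle difference.

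**Figure D3:**
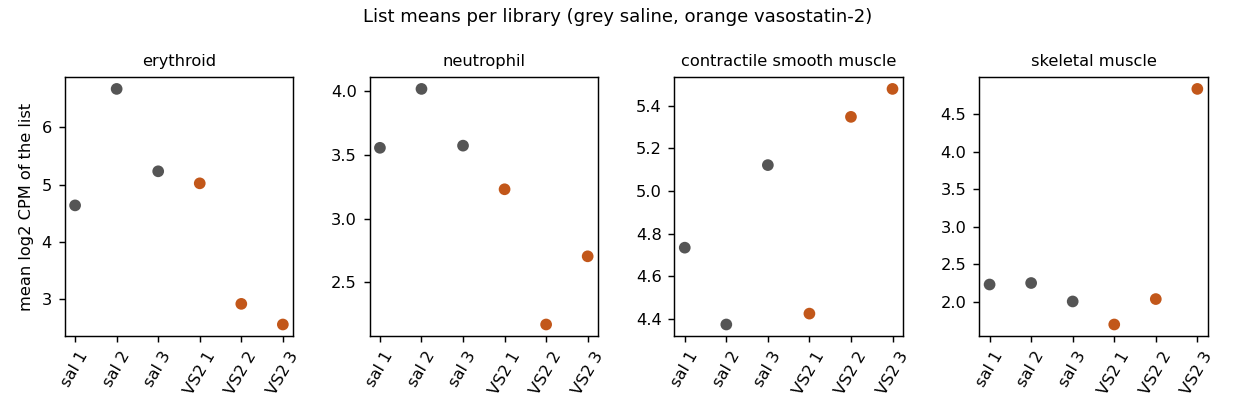
Mean log2 CPM of 4 lists in each library, with saline in grey and vasostatin-2 (VS2) in orange and a separate vertical scale, not starting at 0, in each panel. Erythroid means run from 6.67 in saline replicate 2 to 2.56 in vasostatin-2 replicate 3, and skeletal muscle stands out in vasostatin-2 replicate 3.

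The other 23 lists did not pass. The proliferation lists were near 0, with medians of 0.03 for mitosis and G2/M and −0.01 for DNA replication and G1/S. Extracellular matrix (−0.04), TGF-beta response (−0.06), modulated smooth muscle (−0.07), endothelial (−0.03), interferon response (0.07), oxidative phosphorylation (0.04), fatty acid oxidation (0.04), heat shock and unfolded protein response (−0.05) and dendritic cell (−0.07) genes also had medians within 0.1 of 0. Medians were −0.11 for matrix proteases and inhibitors, −0.06 for platelets and megakaryocytes, 0.14 for adventitial fibroblasts, 0.16 for adipocytes and 0.12 for immediate early genes. They were −0.71 for B and plasma cells, −0.41 for mast cells, −0.17 for epidermal genes, 0.38 for lymph node and lymphatic genes and 0.48 for regenerating skeletal muscle. Schwann cell and nerve genes had a median of −1.16, which rested on saline replicate 3: the list's mean was 5.02 log2 CPM there, 2.63 and 2.79 in the other saline libraries, and 2.77, 3.36 and 2.87 with vasostatin-2. Renin-angiotensin and vasoactive peptide genes had a median of 0.10 and a mean of −0.003. Agtr2 was higher and Nos2, the inducible nitric oxide synthase, lower in that list when adjusted over the list alone, and fry's test for change in either direction gave an adjusted p of 0.00386. The same fry test gave 0.0468 for hypoxia and glycolysis. The median and the direction of the camera test differed in sign for modulated smooth muscle, DNA replication and immediate early genes. Chga was at 4.01 ± 1.22 CPM with vasostatin-2 and 5.47 ± 2.64 CPM with saline (log2 fold change −0.44, SE 0.43). Its log2 fold change was −0.13 without saline replicate 2, −0.23 without vasostatin-2 replicate 2, −0.79 without saline replicate 1 and 0.099 with the erythroid level as a covariate.

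The authors' deposited table gives 98 genes at a q-value below 0.05, 41 higher and 57 lower with vasostatin-2. Of the 113 genes DESeq2 called here, 92 are among those 98 in the authors' deposited table. In 2 of the 98 all counts came from a single library.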

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

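The DESeq2 runs on all genes and without single replicates, the fits without saline replicate 3 and vasostatin-2 replicate 3, the bias-adjusted dispersions and the erythroid covariate were chosen after the data had been seen; the other alternatives were planned. edgeR's count of genes stayed at 0 under other scalings, filters, thresholds and covariates, and ranged from 0 to 2 over the fits that left out a replicate. DESeq2 called 113 genes, 104 on all genes, and 58 without saline replicate 3 and vasostatin-2 replicate 3, of which 31 were among the 113. Leaving out 1 replicate moved the DESeq2 count between 25 and 262. The number of lists called by camera ranged from 11 to 19, but was 0 with an estimated correlation. fry called 0 lists in 1 direction and 2 in its test for change in either direction. Neutrophil, hypoxia and glycolysis, and T and NK cell lists were called in all 14 other settings that kept the preset correlation. Those settings reuse the same libraries, and camera's p-values there do not measure the spread between libraries. The T and NK cell means overlapped between groups (exact permutation p = 0.2). Replicate numbers did not pair the libraries, with same-number correlations of −0.12, 0.03 and 0.03; with the number as a block 0 genes and 12 lists were called, the complement list being lost (adjusted p = 0.109). The skeletal muscle median was between −0.29 (without vasostatin-2 replicate 3) and 1.97 on leaving out a replicate, −0.38 without saline replicate 3 and vasostatin-2 replicate 3, and −0.39 with the erythroid covariate, where the contractile median was −0.52. With that covariate the log2 fold change was −0.015 for Nfkb1 and 0.099 for Chga. It was 0.033 for Hbb-bs and 0.047 for Hba-a1, but both belong to the list that forms the covariate, so values near 0 were built in. Without saline replicate 3 and vasostatin-2 replicate 3 the log2 fold change was −0.17 for Il7r and −0.00031 for Lyz2. Leaving out each replicate gave −0.23 to 0.97 for Il7r, −0.14 to 0.33 for Lyz2 and −0.013 to 0.094 for Nfkb1, none of which passed the test. For these reversals, other than those of skeletal muscle, Hbb-bs and Hba-a1, the cause was not tested.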

Other observations

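The Gene Ontology terms, the clock genes and the tests in this part, other than the scaling by total counts, were chosen after the results had been seen, and every clock gene's values had been looked at before the genes were listed, so none of the tests chosen then is independent of the pattern it examines. Among 2563 Gene Ontology terms with 10 to 500 tested genes, camera with a preset correlation of 0.01 called 8, 5 higher and 3 lower, and with an estimated correlation it called 0. Cholesterol biosynthesis led them, with a median log2 fold change of 0.42 and 22 of 26 genes higher with vasostatin-2 (Benjamini-Hochberg adjusted p = 9.96e-07; adjusted p = 0.999 with an estimated correlation). Nsdhl, which removes a methyl group from sterol intermediates, was at 35.8 ± 2.35 CPM against 25.4 ± 1.88 CPM in saline, Lss, the lanosterol synthase, at 17.9 ± 2.15 against 11.9 ± 1.17 CPM, and Fdft1, the squalene synthase, at 52.5 ± 2.27 against 34.5 ± 7.25 CPM. DESeq2 called these 3, edgeR's quasi-likelihood test none of them after adjustment. The median stayed between 0.35 and 0.50 on leaving out each library.

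Several clock genes of opposite phase lay in opposite directions. Of 15 such genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with 8 at an unadjusted p below 0.05, and DESeq2 called 4, Dbp, Per3, Nr1d1 and Npas2, with Arntl not among them. Dbp was at 21.7 ± 2.54 CPM with vasostatin-2 and 11.1 ± 3.39 CPM with saline, Per3 at 26.7 ± 2.82 against 16.5 ± 2.46 CPM and Nr1d1 at 58.3 ± 3.25 against 37.6 ± 7.42 CPM, while Npas2 was at 9.74 ± 0.118 against 17.2 ± 4.14 CPM and Arntl at 24.8 ± 2.32 against 34.7 ± 8.16 CPM. Per1 and Per2 did not follow, at 49.4 ± 11.2 against 67.3 ± 29.3 CPM and 19.4 ± 2.35 against 19.4 ± 7.82 CPM. An index of the 10 genes of the one phase minus the 5 of the other was higher with vasostatin-2 by 0.85 (95% interval 0.39 to 1.30) on the log2 scale, in 3 of 3 libraries, with an exact two-sided permutation p of 0.1, the smallest 3 against 3 can give. A different hour of tissue collection could give this, as could an effect of treatment on the clock; collection times were not used here, and the genes were picked for showing the pattern, so the explanations cannot be told apart.

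Lower neutrophil transcripts could come with less blood in the vasostatin-2 arteries, since the erythroid list was lower too. The platelet list, another blood component, was mixed. Its mean was 2.12 log2 CPM with vasostatin-2 and 2.17 with saline. DESeq2 called 2 of its 12 members, Pf4 and Ppbp, lower. Within groups the neutrophil mean followed the erythroid mean with a slope of 0.29 (95% interval −0.08 to 0.66, over 6 libraries), below 1. Blood as their whole source would give a slope near 1 only with noise-free erythroid means and a fixed neutrophil to red cell ratio. Neither is known here, so the slope cannot decide. With the erythroid level as a covariate the neutrophil median was −0.45 and its camera adjusted p 0.00731, the highest over its 14 alternatives that kept the preset correlation; with an estimated correlation it was 0.514. Scaling by total counts left the median at −1.11, but it moved fold changes by 0.00085 in the median gene, so it tests nothing about scaling. The erythroid level differed between groups, so the fit with that covariate cannot decide either. Blood as the whole source, a partial share of blood, and fewer neutrophils in the wall after treatment all stay open, the last untested.

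The higher contractile smooth muscle list might reflect the tissue that came with each artery. Without vasostatin-2 replicate 3, the library rich in skeletal muscle transcripts, the list's mean was higher by 0.14 (95% interval −1.27 to 1.56 over libraries), an interval too wide to decide. The contractile mean was lowest in saline replicate 2 and vasostatin-2 replicate 1 (4.37 and 4.43 log2 CPM), with erythroid means of 6.67 and 5.02, and highest in vasostatin-2 replicates 2 and 3 (5.35 and 5.48), with erythroid means of 2.92 and 2.56. With the erythroid level as a covariate the contractile median was −0.52 (camera adjusted p = 2.73e-04), the opposite direction. The erythroid level differed between groups, so that fit cannot separate blood content from treatment. Blood content, a different share of vessel wall between dissections, or a treatment effect stays open.

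With 3 libraries per group there are 10 ways to split the 6, too few for a share under 0.05. edgeR called 0 genes in all 10; at an unadjusted p of 0.05 it gave 1040 and at most 1616, and DESeq2 113 and at most 166, with 2 of the 10 splits giving as many in each case. The largest counts came from setting saline replicate 2 with vasostatin-2 replicates 1 and 2. For lists, camera called 13 in the real grouping and up to 20 in the others, and all 10 splits gave as many. For Gene Ontology terms it called 8 and up to 94, and 9 of the 10 gave as many, so the number of camera calls at the preset correlation does not set the treatment grouping apart from other groupings of these libraries.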
